A study of Mus musculus with 20 samples.

How the data were processed

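The 20 libraries were mouse ChIP-seq libraries and matched background libraries. Per the labels, chromatin was sonicated to about 500 bp, libraries were amplified with 18 cycles of PCR, inserts of 100 to 250 nt were targeted and fragments of 200 to 350 bp were taken from a gel, and sequencing was on the Solexa platform. Per the labels, ES and iPS cells were grown for 1 or 2 passages without feeder cells before fixation, NPCs were derived from 4-day-old embryoid bodies, and liver was whole tissue. The label of the second p300 library names its target p301 in 1 field and p300 in its title and antibody fields, and it was used as p300. Each library was placed in its group from its title, which names the target and the cells.

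Each deposited file lists aligned reads, 1 line per read, as a signed position under the name of a chromosome, where a minus sign marks the reverse strand. The values the authors deposited are positions, neither counts per feature nor a normalised signal, and each file belongs to 1 sample. Reads stand in sections named U0 and U1, with 4.72 to 8.57% of reads in U1, and positions occur repeatedly, so duplicates had not been removed. The aligner, its settings and the genome build are not given in the sources used here. The largest position on each chromosome lay within the chromosome lengths of the mm8 mouse assembly, and coordinates are given 1-based as in the files. The annotation at hand was of another assembly, GRCm38.p6, so no gene name, exon or promoter was attached to a region, the analyses by gene and the gene lists were left out, and promoters were stood in for by H3K4me3 regions.

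Positions on the 19 autosomes, X and Y were used. Repeated positions on the same strand were counted once, and each read was moved 100 bp toward the centre of its fragment, where the median distance between strands was 132 bp over libraries (112 to 178 bp). Enriched regions were called in each library alone in bins of 500 bp. A bin passed where its count exceeded the expectation by a Poisson test at a Benjamini-Hochberg adjusted p of 0.01 and was at least 3-fold over it. The expectation was the larger of the genome mean and the scaled count of the background library averaged over 5000 bp around the bin, and called bins up to 1000 bp apart were joined. Histone marks were set against H3 of the same cells, and p300 and Rfx1 against WCE. No iPS or NPC background library was used here, so their libraries were set against the ES one. Regions overlap where they share at least 1 bp. A region is called distal where it overlaps no H3K4me3 region of ES cells or liver, which leaves promoters active only in MEFs, iPS cells or NPCs among the distal ones. Chance overlap was estimated with 100 circular shifts of all regions along their chromosomes.

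For H3K4me1 and for H3K27ac, regions of all libraries of the mark were merged, those overlapping H3K4me3 were dropped (127944 and 57401 remained), and regions with at least 10 reads in 1 library were kept. Counts were scaled to log2 CPM with a prior count of 2 and a trimmed mean of M-values written for this purpose, and tested with limma-trend, with Benjamini-Hochberg adjustment at 0.05. The 3 and 2 ES libraries give the spread, with 2 and 1 residual degrees of freedom, and each single library is assumed to vary like an ES library. Since the labels do not say that ES libraries came from separate cultures in each case, p-values measure the spread between these libraries, which may be partly technical. Contrasts of 1 mark share the same ES libraries, so no overlap or correlation of calls between contrasts was computed. Comparisons of single libraries carry no p-value. The tests, samples, thresholds, naming rule and alternatives were set before the data were examined, except where the text says otherwise. The rule named, per contrast, the 5 regions with the largest rise and the 5 with the largest fall past an adjusted p of 0.05 with a mean log2 CPM above the median, the 5 H3K4me3 regions highest in each library by ratio with at least 50 reads in 1, and the 10 p300 and Rfx1 regions with the highest fold over background. For p300 the lower fold of the 2 libraries was used, which the rule had left open. For H3K4me3 the rule had been set for genes. Called regions stood in for them, with low counts set to 3 reads, which the rule had not given.

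Libraries of the same group were compared for repeated deposition. Chi-square per degree of freedom over bins was 2.70 for the ES H3K27ac pair, 1.58 for the p300 pair and 2.01 to 4.16 for the H3K4me1 pairs. Each pair thus differed by more than sampling noise and was kept as separate libraries. Positions shared within a pair, over the number expected from read density, stood at 1.60, 1.83 and 1.25 to 1.38 in the same order. Outside enriched regions they stood at 1.77, 1.60 and 1.33 to 1.43. A spread above sampling noise does not exclude shared material, so this was not settled for the H3K27ac and p300 pairs.

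The region caller was tested on simulated data with 20000 enriched bins. With 6 M reads it recovered 4.82%, 67.6% and 99.7% of bins enriched 4-fold, 8-fold and 16-fold, with at most 1.63% false regions in any simulated setting and none called without enrichment. With 2 M reads it recovered 0.0500%, 11.8% and 67.7%, and with 14 M 39.5%, 99.1% and 100%. The limma fits were tested on simulated data drawn from the mean levels of the ES libraries and the real depths. They covered the liver H3K4me1 and NPC H3K27ac contrasts, with 3 models of the spread between regions. The last 2 models were added after the first was seen. Many regions with few ES reads fell below the filter, which left 66662 to 67462 of 118766 and 33162 to 33568 of 51003 regions. Changed regions were picked only among those with more ES reads, so the rates do not cover gains at regions with few ES reads. With 23753 regions changed 4-fold in the H3K4me1 fit, 97.1%, 94.3% and 82.4% were recovered under the 3 models and 11.9%, 9.33% and 6.28% of calls were false. With 10200 regions changed 4-fold in the H3K27ac fit, 96.2%, 94.6% and 77.0% were recovered and 13.5%, 12.2% and 5.71% of calls were false. When changed 2-fold, 62.7%, 43.5% and 0.00421% of the 23753 and 69.5%, 63.9% and 0.127% of the 10200 regions were recovered under the 3 models, and of 200 regions changed 4-fold in the H3K4me1 fit 88.5%, 72.5% and 0%. With 200 regions changed, most calls were false in nearly all settings, from 28.1 to 100% where any were made. Between 7.76 and 13.4% of unchanged regions reached an unadjusted p of 0.05, so the adjusted threshold of 0.05 is nominal.

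Alternatives were limma-voom, scaling by total reads, by median ratio and by reads outside enriched regions in bins of 10000 bp, no filter, all reads kept, a prior count of 0.5, thinning to the shallowest library (2.32 M reads for H3K4me1 and 5.11 M for H3K27ac), leaving out each ES library, and, for regions and overlaps, stricter calls (adjusted p of 0.0001 and 5-fold), another background library, bins of 1000 bp, thinning to 6.27 M reads, an overlap of 50% and a distance of 5000 bp from H3K4me3. Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.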

Results

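Chromatin marks were mapped in mouse embryonic stem (ES) cells and in differentiated cells and tissue by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which an antibody pulls down DNA bound to a modified histone or a protein and the recovered DNA is sequenced. The series held 20 libraries in 16 groups. ES cells contributed 10 libraries and whole liver 5. Mouse embryonic fibroblasts (MEFs) gave 2, neural progenitor cells (NPCs) grown from ES cells 2, and induced pluripotent stem (iPS) cells made from MEFs 1. The targets were H3K4me1, a methyl mark found at enhancers and around promoters; H3K27ac, an acetyl mark of active enhancers and promoters; H3K4me3, a mark of promoters; p300, an acetyltransferase recruited to enhancers; and Rfx1, a transcription factor of the regulatory factor X family. Immunoprecipitated total histone H3 and whole cell extract (WCE), DNA taken without an antibody, served as background. Of all groups, ES H3K4me1 had 3 libraries, ES H3K27ac 2 and ES p300 2; the other groups had a single library, so their differences carry no replicate check of their own. The 3 ES H3K4me1 libraries came from different cells, which were V6.5 ES cells, V6.5 cells with the 4F2A transgene, and inbred C57BL/6 ES cells.

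The deposited files held 158 M aligned reads, from 2.45 M for iPS H3K4me1 to 18.2 M for MEF H3K4me1. ES H3K4me1 had 10.9, 10.0 and 6.37 M reads in replicates 1 to 3, ES H3K27ac 9.20 and 9.31 M, ES p300 7.74 and 9.37 M, ES H3K4me3 7.90 M, ES H3 9.74 M and ES WCE 7.79 M. Liver H3K4me1 had 7.58 M, H3K27ac 5.25 M, H3K4me3 9.24 M, H3 4.44 M and WCE 4.69 M. MEF H3 had 6.51 M, NPC H3K27ac 8.57 M and NPC Rfx1 2.56 M. Reads that repeated a position and strand were counted once. Such repeats made up 70.0% of the ES H3K4me3 reads and 72.5% of the NPC Rfx1 reads, against at most 20.6% in the other libraries, which left 2.37 and 0.705 M distinct reads in these libraries. Intervals are Wilson 95% intervals unless another kind is named, and cover counting error only, because PCR copies are not independent molecules and neighbouring regions are not independent of each other.

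ES cells carried H3K4me1 over more of the genome than any other mark tested there. Enriched regions numbered 69415, 67095 and 74776 in the 3 H3K4me1 libraries, 45797 and 48074 in the H3K27ac libraries and 14840 in the H3K4me3 library, and covered 143, 138 and 138 Mb, 91.0 and 88.1 Mb, and 19.5 Mb. Liver gave 63800 H3K4me1, 33517 H3K27ac and 23387 H3K4me3 regions, MEFs 89785 H3K4me1 regions, iPS cells 40172 H3K4me1 regions and NPCs 27486 H3K27ac regions. These numbers depended on depth and on repeated reads. With all repeated reads kept, the ES H3K4me3 library gave 152205 regions. When every H3K4me1 library was thinned to the 2.32 M distinct reads of the iPS library, an alternative chosen after seeing the data, the ES libraries gave 24196, 28838 and 40666 regions, MEFs 42439 and liver 43720, so the iPS number was within the range of the ES libraries.

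The first comparison asked how far H3K27ac divides the H3K4me1 regions of ES cells that lie away from promoters. Of 60363 ES regions called in at least 2 of the 3 H3K4me1 libraries, 26.4% overlapped an H3K4me3 region of ES cells or liver, and the 44443 others are called distal here. The share with H3K4me3 was 43.8% with all repeated reads kept and 41.6% when H3K4me3 within 5000 bp counted. H3K27ac was called in both ES libraries at 14218 distal regions, 32.0% (31.6 to 32.4), in neither at 22958, 51.7% (51.2 to 52.1), and in only 1 library at 7267. p300 was called in both of its libraries at 51.5% (50.7 to 52.3) of distal regions with H3K27ac in both libraries and at 13.7% (13.3 to 14.2) of those with H3K27ac in neither. The regions with H3K27ac were wider, with a median of 3000 bp against 1000 bp. Per kilobase, they held a mean of 1.96 and 1.77 RPM (reads scaled to library size) of p300 in the 2 libraries, against 1.28 and 1.24 without H3K27ac. WCE was 0.769 against 0.704 and H3 0.595 against 0.578, so p300 was higher by factors of 1.53 and 1.43 while the background libraries were higher by factors of 1.09 and 1.03. Where H3K27ac was called in neither library, it stood at 0.800 and 0.693 RPM per kilobase, so weak marking was not excluded there. With 50% of the region to be covered in place of 1 bp, the share with H3K27ac in both libraries was 14.1%, that with p300 in both was 5.22% in place of 27.6%, and p300 was at 9.35% of regions with H3K27ac in both libraries and at 4.11% of those in neither.

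ES regions with H3K27ac, which were wider, were also more often marked in other cells. H3K27ac of NPCs overlapped 16.1% (15.5 to 16.7) of the ES distal regions with H3K27ac in both libraries and 4.94% (4.67 to 5.23) of those with none. For liver H3K27ac the shares were 14.7% (14.1 to 15.2) and 6.45% (6.14 to 6.78). Wider regions meet more regions by chance, and 100 circular shifts along the chromosomes gave mean shares of 5.70% and 3.08% for NPCs and 7.68% and 4.80% for liver. H3K4me1 itself overlapped 67.4% against 22.9% of the 2 kinds of region in iPS cells, 50.8% against 30.0% in MEFs and 32.7% against 18.9% in liver, with shifted shares of 7.58% and 4.32%, 17.7% and 10.9%, and 13.6% and 8.57%. All of these shares lay above the highest of their 100 shifts. The iPS library had the fewest distinct reads of the H3K4me1 libraries, so weak regions are missed there. Per kilobase, iPS H3K4me1 had a mean of 2.31 RPM at regions without H3K27ac and 3.27 at those with it. The ES libraries had 2.13 to 2.72 and 2.62 to 3.26. The low share called in iPS cells at regions without H3K27ac thus does not show H3K4me1 to be absent there. Relative to the shifted mean, the regions with H3K27ac and those without stood at 2.82 and 1.61 for NPC H3K27ac, 1.91 and 1.34 for liver H3K27ac and 8.89 and 5.30 for iPS H3K4me1, but at nearly the same 2.87 and 2.76 for MEF and 2.41 and 2.21 for liver H3K4me1. Rfx1 of NPCs overlapped 3.98% of the ES regions with H3K27ac, against a shifted mean of 2.56%, and 1.09% of those without, against 1.16%.

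The next comparison asked how much each mark is shared between cell types. With repeated reads counted once, most promoter-type H3K4me3 regions of ES cells were also found in liver, whereas most distal H3K27ac regions of 1 cell type were not found in another. Of ES H3K4me3 regions, 84.0% were called in liver, but of liver H3K4me3 regions only 52.8% were called in ES cells. With all repeated reads kept, 9.76% of the 152205 ES regions were called in liver and 64.0% of liver regions in ES cells. Of the distal H3K4me1 regions of each ES library, 64.0 to 70.8% were called in another ES library, 33.1 to 34.7% in MEFs and 22.3 to 22.9% in liver. Of the distal H3K27ac regions of the ES libraries, 64.3% and 64.9% were called in the other ES library, but 10.2% and 11.4% in NPCs and 11.3% and 10.6% in liver. In the other direction, 26.7% and 29.6% of NPC and 19.3% and 17.9% of liver distal H3K27ac regions were called in the 2 ES libraries. Of the 33443 distal regions of iPS cells, 81.5 to 82.6% were called in each ES library, 36.3% in MEFs, from which the iPS cells were made, and 25.2% in liver. Only 32.8 to 35.7% of ES distal regions were called in the iPS library, which had the fewest reads of all libraries. No test compares these shares, since most rest on a single library.

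**Figure D1:**
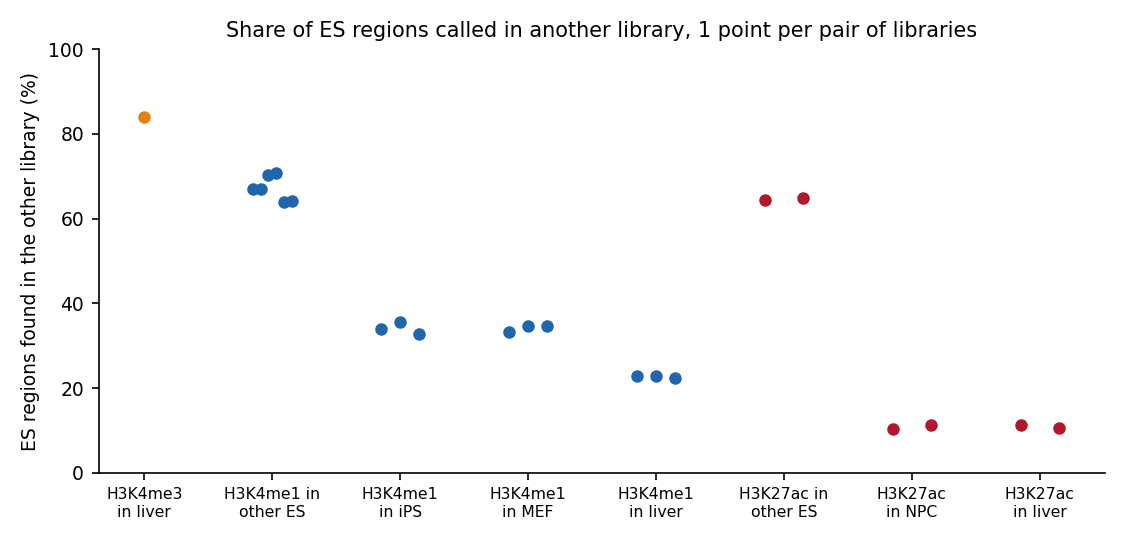
Each point is 1 pair of libraries and gives the share, in %, of the enriched regions of an ES library that overlapped a region of the second library by at least 1 bp, for H3K4me3 and for distal H3K4me1 and H3K27ac. H3K4me3 was shared with liver at 84.0% of regions (9.76% with all repeated reads kept), whereas H3K27ac was shared at 64.3% and 64.9% between ES libraries and at 10.2 to 11.4% with NPCs or liver; the reverse shares, not drawn, were 52.8% of liver H3K4me3 regions and 17.9 to 29.6% of NPC and liver distal H3K27ac regions found in ES.

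Distal H3K4me1 differed widely between ES cells and liver or MEFs. Over the 118766 distal regions tested, limma at an adjusted p of 0.05 called 32545 regions higher and 24476 lower in liver than in ES cells, and 46878 higher and 23290 lower in MEFs. Log2 levels over the regions correlated at 0.906 to 0.929 between ES libraries, 0.262 to 0.313 between liver and ES and 0.252 to 0.281 between MEFs and ES, where regions are not independent replicates. A level at least 2-fold apart was found at 9.89 to 16.7% of regions between ES libraries, 63.9 to 64.2% between liver and each ES library and 72.7 to 73.2% between MEFs and each ES library. Without ES replicate 2, limma called 0 regions higher and 0 lower in liver, at an unadjusted p under 0.05 for 31080 and 22843, and 15058 higher and 4532 lower in MEFs. The higher share of calls was 57.1% in liver and 66.8% in MEFs, and moved between 41.8 and 75.6% and between 58.5 and 83.2% with the scaling between libraries, so the balance of gains and losses was not fixed by these data. The median log2 difference from ES over regions was 0.59 in MEFs, -0.23 in iPS cells and 0 in liver, and other scalings moved it to 0.19 to 0.79, -0.21 to 0.27 and -0.47 to 0.12. Without ES replicate 3 it was 0.04 in MEFs and -0.33 in liver, and after thinning -0.09 in MEFs and -0.21 in liver.

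The distal regions with the largest H3K4me1 gain in liver had few or no reads in the ES libraries. Coordinates are those of the deposited files, whose positions fit the lengths of the mm8 assembly. Region 62737001 to 62744500 of chromosome 4 had 143 CPM (counts scaled to library size) in liver, from 635 reads, against 1.22 ± 0.332 in ES (SD, n = 3), a log2 difference of 6.92 (SE 0.412, limma adjusted p = 0.00517). Region 122466001 to 122482000 of chromosome 2 had 162 CPM from 719 reads against 1.56 ± 0.619, a log2 difference of 6.80 (SE 0.592, limma adjusted p = 0.00534). The other 3 of the top 5, on chromosomes 7, 12 and 2, had 235 to 357 reads in liver and 0 to 15 in each ES library. Among the regions with the largest loss, region 107426501 to 107435000 of chromosome 12 had 161 to 222 reads in each ES library and 0 in liver, and region 120991001 to 121001500 of chromosome 5 had 237 to 357 reads and 1 in liver. The other 3, on chromosomes 4, 8 and 11, had 87 to 340 reads in each ES library and 0 or 1 in liver. All 10 of these calls were lost without ES replicate 2, and 1 of them without ES replicate 1.

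In MEFs, region 76092001 to 76098000 of chromosome 10 led the gains with 76.5 CPM from 879 reads against 1.01 ± 0.466 in ES (SD, n = 3), a log2 difference of 6.38 (SE 0.724, limma adjusted p = 0.00676). Region 62794501 to 62799000 of chromosome 4, close to the leading liver gain on that chromosome, had 55.8 CPM from 641 reads against 0.852 ± 0.355, a log2 difference of 6.13 (SE 0.591, limma adjusted p = 0.00605). The other 3, on chromosomes 16, 11 and 7, had 327 to 757 reads in MEFs and 0 to 11 in each ES library. The losses were led by region 80944501 to 80953500 of chromosome 11, with 232 to 323 reads in each ES library and 1 in MEFs, and region 66743501 to 66752000 of the same chromosome, with 288 to 337 reads and 2 in MEFs. Those on chromosomes 3, 2 and 4 had 108 to 481 reads in each ES library and 0 to 3 in MEFs. Without ES replicate 2, 3 of these 10 calls were lost.

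iPS cells resembled ES cells in distal H3K4me1. Log2 levels of the iPS library correlated with the ES libraries at 0.882 to 0.894 over regions, and 22.1 to 26.1% of regions were at least 2-fold apart. limma called 0 regions higher and 0 lower in iPS than in ES cells; at an unadjusted p under 0.05 it called 3088 higher and 12318 lower, and limma-voom gave 0 and 0 adjusted and 2401 and 1319 unadjusted. With all libraries thinned to the 2.32 M distinct reads of the iPS library, limma still called 12255 higher and 12234 lower regions in liver and 12384 and 11776 in MEFs, but 0 and 0 in iPS cells, with 1172 and 1688 at an unadjusted p under 0.05. A count of 0 excludes neither small differences nor large ones at few regions.

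Distal H3K27ac levels of NPCs and liver lay further from those of ES cells than the ES libraries lay from each other. The 2 ES libraries correlated at 0.910 over regions and were at least 2-fold apart at 12.2% of them, whereas NPCs correlated with them at 0.236 and 0.279 and were 2-fold apart at 60.3% and 58.3%, and liver correlated at 0.107 and 0.071 and was 2-fold apart at 73.1% and 73.4%. Over 51003 distal regions tested, limma at an adjusted p of 0.05 called 6623 higher and 5171 lower in NPCs than in ES cells, and 10279 higher and 12725 lower in liver. These calls rest on 1 NPC and 1 liver library and a spread with 1 residual degree of freedom. limma-voom called 0 regions in either contrast and direction, with 10079 higher and 3498 lower in NPCs and 11569 higher and 2944 lower in liver at an unadjusted p under 0.05, and without the filter on low regions limma called 0 in NPCs. The higher share of calls was 56.2% in NPCs and 44.7% in liver, and moved between 27.04 and 66.27% and between 31.6 and 50.9% with the scaling. The median log2 difference from ES over regions was -0.39 in NPCs and -0.81 in liver, and other scalings moved it to -1.22 to -0.19 and -1.39 to -0.57.

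Among distal regions that limma called higher for H3K27ac in NPCs, region 97073001 to 97078000 of chromosome 4 had 80.7 CPM from 370 reads against 0.525 ± 0.0590 in ES (SD, n = 2), a log2 difference of 7.27 (SE 0.257, limma adjusted p = 0.0439), and region 85267501 to 85269500 of chromosome 6 had 74.7 CPM from 342 reads against 0.605 ± 0.0549, a log2 difference of 6.95 (SE 0.228, limma adjusted p = 0.0439). The other 3 gains, on chromosomes 6, 5 and 10, had 177 to 366 reads in NPCs and 0 to 7 in each ES library. Region 9395501 to 9400500 of chromosome 15 led the losses with 218 and 285 reads in the ES libraries and 0 in NPCs, followed by region 49117501 to 49120500 of chromosome 9 with 190 and 246 reads and 0 in NPCs. The other 3, on chromosomes 1 and 4, had 135 to 378 reads in each ES library and 0 or 1 in NPCs. All 10 NPC calls were lost with limma-voom and without the filter, and 2 of them with a prior count of 0.5.

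In liver, regions 51288501 to 51293500 and 51250001 to 51257000 of chromosome 18, which lie close together, had 228 and 207 H3K27ac reads against 0 or 1 in each ES library. Region 60179501 to 60187000 of chromosome 3 had 93.9 CPM from 357 reads against 0.606 ± 0.174 in ES (SD, n = 2), a log2 difference of 7.31 (SE 0.399, limma adjusted p = 0.0273). Gains on chromosomes 12 and X had 276 and 222 reads in liver and 0 to 4 in each ES library. All 5 leading losses, on chromosomes 11, 14, 4 and 15, had 0 reads in liver. They were led by region 63083501 to 63089500 of chromosome 11 with 412 and 596 reads in the ES libraries and region 98229501 to 98243500 of chromosome 14 with 409 and 590, and the other 3 had 299 to 408 reads in each ES library. All 10 liver calls were lost with limma-voom.

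A further comparison, chosen after seeing the data, asked what state the H3K27ac regions of NPCs and liver had in ES cells. Most had neither mark called in ES cells, though fewer than among shifted regions. Here and below, neither mark means that neither was called, and a region not called may hold a weak mark. Even between the 2 ES H3K27ac libraries, only 64.3% and 64.9% of distal regions were called in the other. Of 13882 distal H3K27ac regions of NPCs, 23.0% (22.3 to 23.7) had H3K27ac in both ES libraries, 10.3% in 1 library, 11.2% (10.7 to 11.7) had H3K4me1 without H3K27ac and 55.6% (54.7 to 56.4) had neither. Shifted regions gave means of 4.53%, 2.31%, 4.59% and 88.6%. Of 16691 distal H3K27ac regions of liver, 14.7% (14.2 to 15.3) had H3K27ac in both ES libraries, 7.70% in 1, 11.2% (10.7 to 11.7) had H3K4me1 alone and 66.4% (65.7 to 67.1) had neither, against shifted means of 4.90%, 2.43%, 4.71% and 88.0%. With 1 library of each, and with NPC regions called against the ES background but liver regions against that of liver, the shares were not tested between NPCs and liver.

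**Figure D2:**
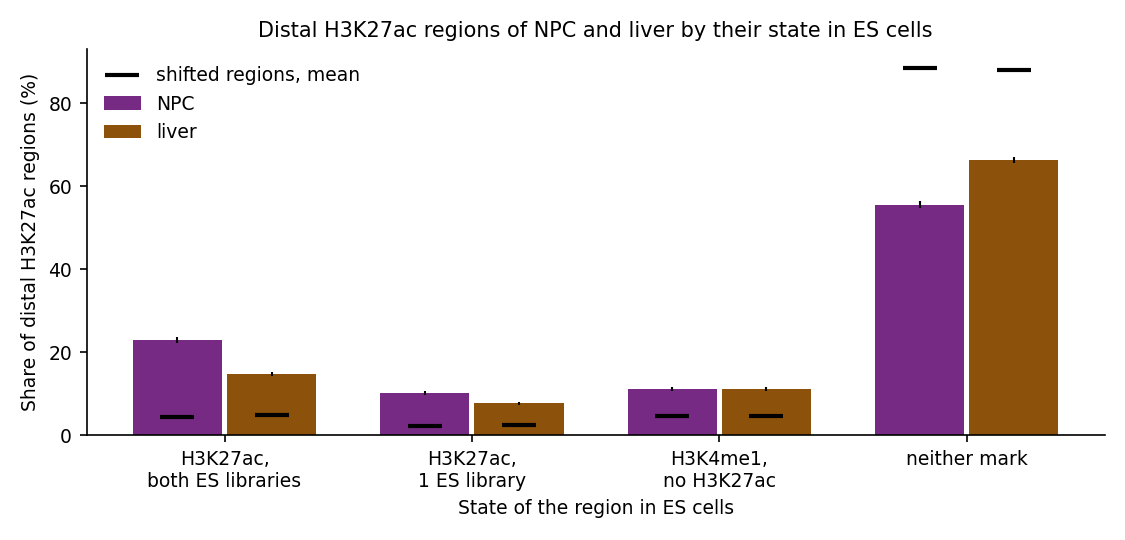
Bars give the share, in %, of the distal H3K27ac regions of NPCs (13882 regions) and liver (16691 regions) that fell in each state in ES cells, thin lines the Wilson 95% interval, and horizontal marks the mean of 100 circular shifts. The largest share had neither mark called in ES cells, 55.6% in NPCs and 66.4% in liver, below the shifted means of 88.6% and 88.0%.

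H3K4me3 was compared between liver and ES cells with 1 library each, so no test was made. Of 25634 merged H3K4me3 regions, 12438 were called in both, 10935 in liver alone and 2261 in ES alone. Called regions held 81.5% of the distinct reads of the liver library and 40.4% of those of the ES library. Ratios in RPM include this difference between the libraries, and it was not separated from a difference in the mark. Of the 15068 regions with at least 50 reads in 1 library, 42.8% differed by less than 2-fold in RPM, 4185 were at least 4-fold higher in liver and 251 at least 4-fold higher in ES. The median region was 1.09 higher in liver on the log2 scale, and after scaling to the median ratio of all merged regions with reads in both libraries, which left a median of 0.09 over these regions, 60.6% were within 2-fold, with 1990 at least 4-fold higher in liver and 530 in ES. Ranked by ratio with lower counts set to 3 reads, an order that follows the reads of the higher library, the liver excess was led by region 8003001 to 8011500 of chromosome 12, with 1938 reads in liver and 3 in ES cells, followed by region 32239001 to 32247000 of chromosome 2 with 1890 and 3. Region 163237501 to 163243500 of chromosome 2 had 1840 and 0, which is 181-fold in RPM with the lower count set to 3 reads. The exact 95% interval at that count was 61.8 to 878. The ES excess was led by region 122673001 to 122676000 of chromosome 6, with 205 reads in ES and 3 in liver. Region 41651501 to 41655000 of chromosome 3 had 201 and 0, which is 227-fold in RPM at the same floor (exact 95% interval 76.6 to 1111). The other named regions had 1868 and 1782 reads in liver against 2 and 1, and 159, 142 and 141 in ES against 3, 0 and 0.

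p300 in ES cells lay at narrow sites that mostly carried H3K4me1. Of 53715 p300 regions called in either library, 29587 (55.1%) were called in both, and 36.7% of those overlapped H3K4me3. Of the 18738 distal ones, 88.7% overlapped an ES H3K4me1 region, 52.5% had H3K27ac in both libraries and 33.3% in neither. Each centre was set at the 500 bp bin with the most reads of p300 replicate 1. The regions had been called for p300, so a p300 peak at the centre was built in. Around the centres, p300 read density was 8.04 and 8.13 times that at 5 kb in the 2 libraries. H3K4me1 was 2.38 to 2.62 times and H3K27ac 2.64 and 2.499 times as high, H3 0.913 times and WCE 1.29 times. Region 70805501 to 70806000 of chromosome 17 ranked first by the lower fold of the 2 libraries, with 161 and 172 p300 reads and 0 in WCE, 120-fold and 108-fold over the expected background. Region 107028001 to 107028500 of chromosome 7 had 142 and 255 reads against 1 in WCE, 106-fold and 160-fold. The other 8 of the top 10, on chromosomes X, 1, 18, 11, 10, 2 and 7, were 71.7-fold to 104-fold over background in replicate 1 and 72.0-fold to 97.3-fold in replicate 2.

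**Figure D3:**
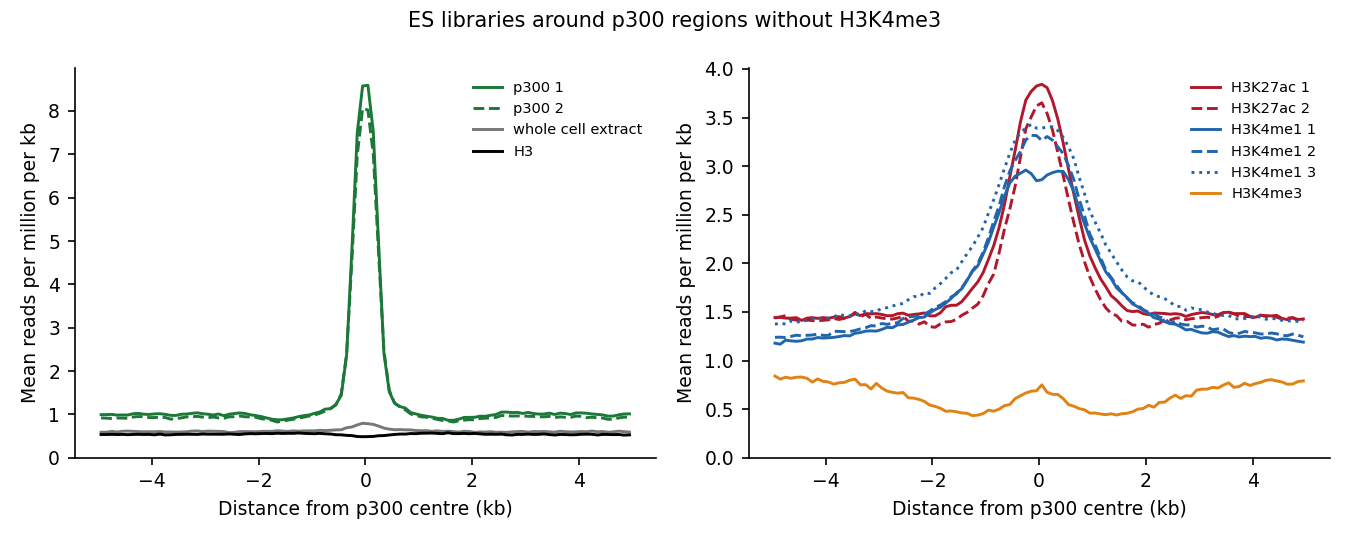
Lines give the mean read density, in RPM per kb, of each ES library against the distance in kb from the centre of the 18738 distal p300 regions. p300 and WCE with H3 are shown at left and the histone marks at right. p300 peaks within 1 kb at 8.04 and 8.13 times its level at the edge. The centre is the 500 bp bin with the most reads of p300 replicate 1, so this peak is built in.

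Rfx1 in NPCs was found chiefly at promoter-type regions. Of 13350 Rfx1 regions, 72.9% overlapped H3K4me3 of ES cells or liver and 72.1% overlapped H3K27ac of NPCs, against 2.58% and 2.42% for shifted regions, and 40.5% overlapped p300 regions of both ES libraries. Among the 1000 regions with the highest fold over background, 89.0% overlapped H3K4me3 and 93.9% NPC H3K27ac. Of NPC H3K27ac regions, 34.3% overlapped an Rfx1 region. The strongest was region 108386001 to 108386500 of chromosome 8 with 331 Rfx1 reads against 1 in ES WCE, followed by region 4879501 to 4880000 of chromosome 16 with 328 against 0 and region 139714001 to 139714500 of chromosome 5 with 292 against 0. The other 7 of the top 10, on chromosomes 2, 1, 3, 8 and 7, had 244 to 389 reads against 0 to 2, and 9 of the 10 overlapped H3K4me3. No NPC background library was used here, and with all repeated reads kept 92238 regions were called, of which 20.4% overlapped H3K4me3 and 15.5% NPC H3K27ac.

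Reads outside enriched regions were compared between chromosomes, after an uneven density was seen. Relative to liver, the ES H3 and WCE reads were 1.17 times as dense on chromosome 8 and 0.973 to 1.02 times on each other autosome. Relative to the autosomes of the same library, chromosome 8 stood at 1.13 to 1.24 in the 8 ES libraries from V6.5 cells without the transgene, at 1.01 in the V6.5 cells with the 4F2A transgene and at 1.04 in the C57BL/6 ES cells. The excess was thus in 8 of the 10 ES libraries, and levels on this chromosome taken from those libraries include it.

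**Figure D4:**
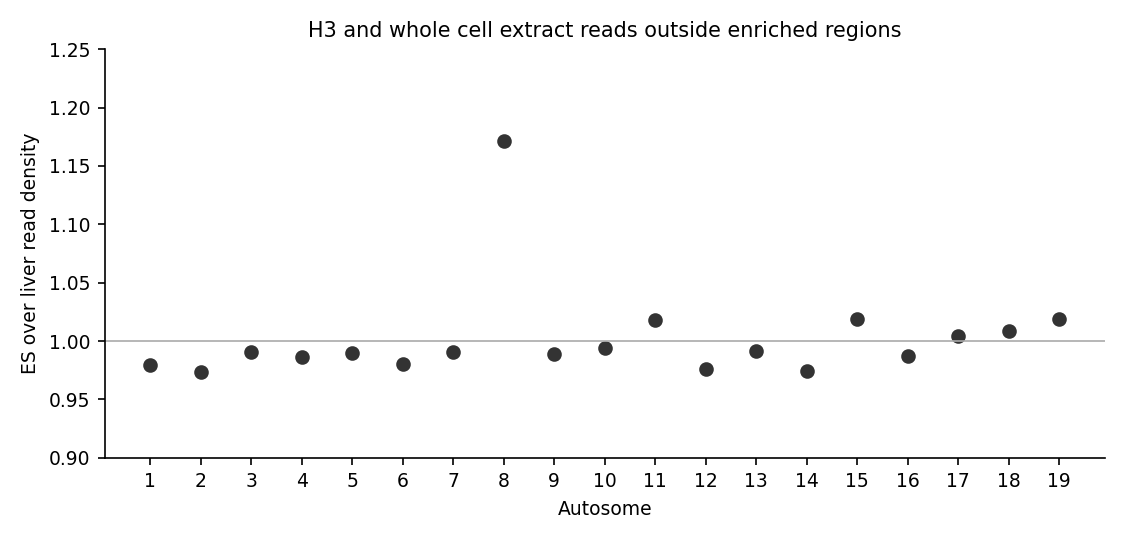
Points give, for each autosome, the density of H3 and WCE reads outside enriched regions in ES cells over that in liver, where the grey line marks equal density and the vertical axis starts at 0.90. Chromosome 8 stands at 1.17, and the other autosomes lie between 0.973 and 1.02.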

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

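The comparison given here was not planned, and no explanation of it was tested. Mitochondrial reads, which no comparison used, made up 0.0934% of the ES H3K4me3 reads, 7381 of 7902095 (Wilson 95% interval 0.0913 to 0.0956), above the 0.0577% of the ES whole cell extract. The whole cell extract of liver had 0.145%, and the other immunoprecipitated libraries had at most 0.0272%.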

How the results depend on the processing

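The thinned counts of regions per H3K4me1 library, the states in ES cells of NPC and liver H3K27ac regions and the settings for shares between cell types were alternatives chosen only after seeing the data; the others were planned. Of 335 alternative values of counts and shares, 188 stayed within 1.5 times the count or within a spread or counting interval, and 147 moved. The 188 include the iPS counts of calls, which were 0 in the main fit and in every alternative. A count or share has no sign, so none could be labelled as reversed. The balance of calls did turn in places. With total reads, the higher share of H3K4me1 calls in liver was 41.8% in place of 57.1%. For the shares at least 2-fold apart and for H3K27ac at distal p300 regions, the spread was that of the values without 1 library. Those values were thus judged by their own spread. Of 380 alternatives for the named distal regions, 334 kept direction and call, 46 kept direction but lost the call and 0 reversed. Of 60 for the named H3K4me3, p300 and Rfx1 regions, 59 stayed and 1 moved. The cause was not tested, except that fewer samples, fewer reads or a stricter rule act by construction. Leaving out 1 ES H3K4me1 library gave 0 to 19349 liver-higher, 0 to 23265 liver-lower, 15058 to 29052 MEF-higher and 4532 to 23801 MEF-lower regions, with the lowest values without replicate 2 in each, and shares at least 2-fold apart of 28.2 to 35.0% and 29.1 to 36.8% in liver, 37.9 to 46.4% and 26.7 to 35.3% in MEFs and 3.77 to 4.42% and 14.5 to 20.4% in iPS cells. Leaving out 1 ES H3K27ac library gave 25.2 to 25.6% and 34.6 to 37.3% in NPCs and 27.3 to 28.2% and 47.3 to 47.5% in liver, with no residual degrees of freedom and so no test. Without each H3K4me1 library, the ES distal regions had H3K27ac in both libraries at 38.2 to 38.5%, in neither at 44.3 to 45.0% and p300 at 31.6 to 33.7%, p300 was at 53.0 to 54.7% of those with H3K27ac in both and at 15.4 to 17.7% of those in neither, and 26.6 to 28.5% of regions had H3K4me3. Each p300 library alone gave 39014 to 45004 regions, with H3K27ac in both libraries at 41.2 to 41.3% of distal ones.

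With total reads and no composition factor, 21485 regions were higher in liver for H3K4me1, 14818 lower in NPCs and 20317 lower in liver for H3K27ac. Scaling by reads outside enriched regions gave 18269 higher and 5887 lower in liver and 7343 lower in MEFs for H3K4me1, and 14498 lower in NPCs. Median-ratio scaling gave 3381 lower in NPCs. limma-voom gave 0 higher and 0 lower for both H3K27ac contrasts, and no filter gave 0 and 0 in NPCs. Thinning to the shallowest library gave 12255 higher and 12234 lower in liver and 12384 higher and 11776 lower in MEFs, over 53382 regions tested.

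Stricter calls gave 19317 regions in iPS cells, 28998 and 25422 in the p300 libraries, 33.7% of ES distal regions with H3K27ac in both, 22.8% with H3K4me3, p300 at 47.9% of regions with H3K27ac, H3K27ac at 48.3% of distal p300 regions, Rfx1 overlaps of 79.9% with NPC H3K27ac and 80.4% with H3K4me3, and 64.0% and 74.3% of NPC and liver H3K27ac regions with neither mark in ES. The other background library gave p300 at 31.9% of ES distal regions, H3K4me3 at 24.1%, p300 at 58.8% and 16.6% of regions with and without H3K27ac, H3K27ac at 48.7% of distal p300 regions, Rfx1 overlaps of 69.0% and 70.9%, and 58.7% and 68.0% with neither mark. All reads kept gave 152205 ES H3K4me3 and 92238 Rfx1 regions, H3K27ac in both at 24.5% and in neither at 59.2%, p300 at 23.4%, p300 at 46.2% of regions with H3K27ac, H3K4me3 at 43.8%, Rfx1 overlaps of 15.5% and 20.4%, 29.7% of H3K4me3 regions within 2-fold, and 57.6% and 67.6% with neither mark. An overlap of 50% gave 14.1%, 72.6% and, for p300, 5.22%, with p300 at 9.35% and 4.11% of regions with and without H3K27ac. Thinning to 6.27 M reads gave 25.8% with H3K4me3 and 58.6% and 69.8% with neither mark. Bins of 1000 bp gave 53.0% with H3K27ac in neither, 29.4% with H3K4me3 and p300 at 53.5% of regions with H3K27ac. A distance of 5000 bp from H3K4me3 gave 41.6% with H3K4me3, p300 at 53.9% of regions with H3K27ac, and 60.01% and 69.3% with neither mark. Depth-matched H3K4me1 regions numbered 24196, 28838 and 40666 in ES and 42439 in MEFs. The median ratio gave 60.6% of H3K4me3 regions within 2-fold, 1990 at least 4-fold higher in liver and 530 in ES.

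Shares found in other cells are means over pairs of libraries. With all reads kept, the share of ES H3K4me3 regions found in liver fell from 84.0 to 9.76%, and that of liver regions found in ES was 64.0% in place of 52.8%; stricter calls gave 87.5% and 55.5%, and thinning 54.9% for the second. Under stricter calls, thinning and all reads kept, ES distal H3K4me1 was shared at 63.2, 62.5 and 62.8% between ES libraries (67.2% before), 24.2, 37.2 and 30.0% with iPS cells (34.1%) and 27.3, 27.9 and 31.8% with MEFs (34.2%), and iPS regions with ES at 80.7, 74.3 and 78.1% (82.0%). With liver it was 20.9% under stricter calls and 20.4% with all reads (22.6%). In the same order, distal H3K27ac was shared at 67.1, 61.7 and 59.7% between ES libraries (64.6%), 9.61, 11.5 and 10.3% of ES regions with liver (10.9%), 22.9, 25.4 and 25.4% of NPC (28.1%) and 14.4, 16.1 and 16.7% of liver regions with ES (18.6%). For ES regions in NPCs it was 9.77% under stricter calls and 9.48% with all reads (10.8%).

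No paired analysis was possible because the titles number only the ES H3K27ac and ES p300 libraries, different targets that no test compares, and the numbers of the ES H3K4me1 libraries are only names. Not run, of what was set beforehand, were all fits by gene with their gene lists and windows around transcription starts, which need an annotation of the assembly, the size-factor count tool, set beforehand only for deposited counts per feature and replaced by limma-voom, and tests without 1 ES H3K27ac library. Depth limits the iPS, ES H3K4me3 and Rfx1 libraries most, where weak regions are most easily missed.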

Other observations

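All comparisons in this part were chosen after seeing the data; of the tests of explanations, those of the chromosome 8 windows, of H3K4me3 depth and of region width had their bounds set before their results were seen, and those of the other autosomes, of the whole cell extract ratio and of the difference at a single width did not. At distal H3K4me1 regions higher in ES cells than in MEFs, iPS cells stood nearer to ES cells than liver did. Distal H3K4me1 regions were picked where 1 ES library stood at least 4-fold above or below MEFs, and the libraries not used for picking were then compared. At regions higher in ES, the other ES libraries had a median of 2.503 to 2.624 over MEFs on the log2 scale, iPS cells 2.49 to 2.57 and liver 0.50. Of these regions, 88.3 to 91.7% were nearer to ES than to MEFs in iPS cells, against 91.6 to 97.4% in the other ES libraries and 24.6 to 26.2% in liver. The liver median of 0.50 is the log2 ratio of 1 read in liver (0.4705 CPM) to 1 read in MEFs (0.3319 CPM). It thus lies near the floor and reflects depth and the prior count. Picking against the same MEF library moves any library away from MEFs, so only the difference between iPS cells and liver is read here. At regions higher in MEFs, where liver was nearer to ES at 68.1 to 72.1% of regions, no position of iPS cells was read.

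Liver had H3K27ac at 29.5% (29.0 to 29.9, Wilson 95% interval) of its distal H3K4me1 regions, below the 32.6 to 37.5% of the 6 pairs of 1 ES H3K4me1 and 1 ES H3K27ac library, with 5.11 M distinct H3K27ac reads in liver against 8.88 and 8.51 M in ES, so depth was not matched. MEF H3 reads outside enriched regions were 1.46 times as dense on X and 0.617 times on Y as in the 4 ES and liver background libraries, with autosomes at 0.906 to 1.04 times. Relative to the autosomes, MEF H3K4me1 had an X density of 0.329, within the 0.290 to 0.356 of the ES H3K4me1 libraries, and a Y density of 0.0421, against 0.0479 to 0.168.

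The 8 ES libraries from V6.5 cells without the transgene held more reads on chromosome 8 than the other libraries. The largest departure of another autosome was 0.155 of that of chromosome 8, so among autosomes the excess lay on this one. Chromosome 8 had been picked because it stood out, so this is no independent test of a bias that acts on all chromosomes. An extra copy of chromosome 8 in part of the V6.5 cells without the transgene is a candidate explanation. Of the 27 windows of 5 Mb, 100% exceeded the bound set beforehand, against 9.77% of 471 windows elsewhere, with window ratios of 1.09 to 1.27. The excess thus ran along the whole chromosome. At a ratio of 1.17 over the chromosome most windows were likely to pass. Any cause that acts on the whole chromosome would pass too, so the windows do not single out an extra copy. If an extra copy were the cause, the excess would correspond to 1 extra copy in 34.3% of cells. The 12 other libraries, which include the V6.5 cells with the transgene at 1.01, stood at 0.959 to 1.047, and a gain in culture was not tested against other differences between the stocks.

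Liver gave 1.58 times as many H3K4me3 regions as ES cells with repeated reads counted once, but 22898 against 152205 with all reads kept. With the liver library thinned to the 2.37 M distinct reads of the ES library, the ratio was 1.247, just under the bound set beforehand, and 10 draws added after that value was seen gave 1.241 to 1.247. Fewer distinct reads may thus account for at least part of the difference, as far as that bound goes. The thinned liver library still gave 18506 regions against 14840 in ES cells. Thinning does not match enrichment, since called regions held 81.5% of distinct reads in liver and 40.4% in ES at full depth. With 1 library of each, the ratio left over had no replicate spread to be judged by. After thinning, 80.2% of ES regions were found in liver and 63.9% of liver regions in ES. A difference between tissues stays open and was not tested.

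p300 overlapped distal H3K4me1 regions with H3K27ac more often than those without. Sites that give more reads in any library were argued against, since WCE was higher by a factor of 1.09 only, against 1.53 and 1.43 for p300. Among regions of like width, the shares differed by 4.58 percentage points at 500 bp, and by 8.68, 15.9, 24.7 and 40.9 points in the 4 wider classes. The bound of 5 points set beforehand was missed at 500 bp, but regions of 1 called width leave no room for called width. The difference there was 2.42 to 7.24 points (Newcombe 95% interval), and 6.60 to 10.9 at 1000 bp, which argues against called width as the whole cause. Called width goes in steps of 500 bp, so the true breadth of a mark was not matched. H3K4me1 level was not matched either, with means over all widths of 2.62, 2.79 and 3.26 RPM per kilobase with H3K27ac against 2.13, 2.15 and 2.72 without. A tie between p300 and H3K27ac in these cells may remain beyond called width, as a hypothesis from 2 libraries of each.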
